A study of Homo sapiens with 4 samples.

How the data were processed

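RNA of 2 stably transduced populations of A549 cells, one overexpressing miR-210 and one the control miR-67, was compared on 4 two-colour arrays. Per the labels, RNA had been extracted with Qiagen chemistry and 0.2 µg of each RNA had been amplified and labelled with Agilent's QuickAmp kit. Each time, 24 h and 48 h after plating, has 2 arrays in dye swap. The labels give the dye of each population on each array, and from them every ratio was turned to miR-210 over miR-67. All 4 arrays lie on 1 slide, so there was no slide to test as a batch.

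Per the file headers, the scanner images were quantified with Agilent Feature Extraction 10.7.3.1 on array design 028004, whose probe coordinates refer to hg19. The deposited scanner files give the spot intensity of each channel as the mean of its pixels, without background subtraction, and the intensity of the local background. They also give processed intensities, which the software had background-subtracted, detrended and dye-normalized, per the file headers, and a log10 ratio of Cy5 over Cy3 of those signals. The authors also deposited a value table whose method, scale and centring are not given in the sources used here. Its columns have means of 0 and medians of −0.0127 and −0.00351 for replicates 1 and 2 of 24 h, and 0.00863 and −0.00800 for those of 48 h. Set against the log10 ratios of the same arrays, the columns of the deposited table correlated at 0.934, 0.930, 0.880 and 0.917, and their slopes on the log2 scale were 1.05, 0.892, 1.38 and 0.879. They were read as log2 ratios of Cy5 over Cy3 centred on their mean. How the authors normalized them stays unknown.

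Each array carries 62976 spots, of which 58717 are not controls and represent 42405 probes. Signals were background-corrected with normexp (offset 50), which fits on all spots, and normalized within each array by loess in limma 3.58.1 under R 4.3.3, with the R package data.table (version 1.17.8) for reading. Control and outlier spots had weight 0 in the loess fit and were left out afterwards. No spot was saturated. Spots of 1 probe were averaged. A probe was kept if it stood well above background, by Agilent's mark, in the miR-210 channel or in the miR-67 channel on both arrays of at least 1 time, which kept 25932 probes. Outlier marks left 451 probes without a value on an array, and these were not tested. Probes were named through their RefSeq accession (24826 probes), their symbol (1188) or an older symbol (483) in the RefSeq table of assembly GRCh38, from which only names and gene types were taken, and 15908 kept the name in the file. The brightest kept probe stood for a gene, which gave 21155 genes. Probes of E2F3 (−0.24 to −0.092) and CXCL1 (−0.48 to −0.23) had the same sign but differed in size. Probes of the same gene differed in sign for APP, ACTL8, TAF5L, RRM2, ATF3, CANX, VEGFA and MNT.

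The tests were fixed before the data were examined, as were the alternatives and the rule for named genes. The main test averaged the dye-swapped pair of each time, in which a dye effect of a probe cancels, and tested the mean of the 2 pair means against 0 with limma (lmFit and eBayes), with 1 residual degree of freedom. Values given with SE come from this fit unless a fit with a dye effect is named. The tests for 24 h, for 48 h and for 48 h minus 24 h used all 4 arrays in 1 limma fit with a coefficient per time and 2 residual degrees of freedom. A further fit, also fixed beforehand, added a dye effect for each probe, with 1 residual degree of freedom. Since replicate numbers coincide with the dye orientation, that fit is also the fit with the replicate number as a block. Across genes, arrays of the same orientation correlated at 0.635 and 0.688, and the arrays of a swap pair at 0.143 at 24 h and −0.0857 at 48 h. All p-values across genes were adjusted by Benjamini-Hochberg, and adjusted p-values are from limma unless camera is named. Genes named for both times were the 12 largest rises and 12 largest falls among called genes with the same sign on all 4 arrays, a signal well above background in the higher channel on all 4 arrays and a gene symbol. For each list up to 4 called members with the largest ratios could be named, or the 2 brightest where none was called, and genes described as central to miR-210 were always given. One list member that this rule names is not reported here. PIM1, SIN3A, CDKN1A, FAS, TNFAIP3, SOD2, HMOX1, the noncoding RNAs other than those among the 12 largest rises, and the genes of single times fall outside this rule and were picked after their values were seen.

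The 27 gene lists were written from general knowledge: described miR-210 targets, respiratory complex I, complexes II to V, iron-sulfur assembly and iron handling, other genes that respond to hypoxia-inducible factor, glycolysis and lactate export, G1/S and DNA replication, G2/M and mitosis, p53-responsive genes, repair of DNA double-strand breaks, apoptosis regulators, interferon-stimulated genes, NF-kB-responsive cytokines, cholesterol synthesis, fatty acid oxidation, the tricarboxylic acid cycle, the integrated stress response, the unfolded protein response, NRF2-responsive genes, MYC-responsive ribosome biogenesis, cytosolic ribosomal proteins, mesenchymal and matrix genes, epithelial junctions, lung epithelial differentiation, and leukocyte, fibroblast and endothelial markers. Lists were tested with camera over the mean of both times, with a preset correlation of 0.01 between genes and, as an alternative, with an estimated one. Alternatives for every result were Agilent's processed signals, median centring without loess, no background correction, the authors' table, no filter on dim probes, a filter requiring both channels well above background on all 4 arrays (22394 probes), the average of all probes of a gene, and leaving out each array in turn. Where an array was left out, the lone array of that time was assumed to vary like the others.

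The tests were tested on simulated data with the real genes and dye effects, in which 67, 67 and 66 genes were changed by a log2 of 0.2, 0.4 and 0.8. The dye effect of a simulated gene had the same size on every array, so it cancelled in each pair mean. The simulated spread was drawn from the fit with a dye effect. The rates below therefore do not show how the tests fare where a dye effect differs between arrays. For both times, the fit of pair means recovered 53.7% of genes changed by a log2 of 0.2 and 100% of those changed by 0.4 or 0.8, and 14.6% of its calls were unchanged genes, above the nominal rate. The fit of 4 arrays recovered 0% at 0.2 and 0.4 and 80.3% at 0.8. For 48 h alone it recovered 0% at each size, and with the dye effect 10.4%, 91.0% and 100%, with 18.8% of calls being unchanged genes. For 48 h minus 24 h, the fit of 4 arrays recovered 0% at each size and that with the dye effect 2.99%, 43.3% and 100%, with 24.2% of its calls being unchanged genes. camera with the preset correlation called a simulated list of 25 genes shifted by −0.2 (adjusted p of 1.45e-38). With an estimated correlation camera did not (adjusted p of 0.663), and 0 unshifted lists were called either way. The simulated genes varied independently, so this could not show how often lists of correlated genes are called falsely. In the data the estimated correlation ran from −0.099 for leukocyte markers to 0.486 for cytosolic ribosomal proteins, with 0.189 for the p53 list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The search for microRNA sites in 3' UTRs was not run, and 3' UTR sequences were not used here. Sites were searched in the 60-base probe sequences in its place, and list tests with a dye effect were added, both after the data were seen.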

Results

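Gene expression was compared between 2 populations of A549 cells, a human lung adenocarcinoma line. One carried a lentiviral vector for miR-210, a microRNA that accumulates when oxygen is low, and the other carried a vector for the control miR-67, a microRNA of the worm C. elegans. Both had been selected with puromycin. Total RNA was taken 24 h and 48 h after plating, and the RNA of the 2 populations was hybridised together on two-colour Agilent arrays of 60-base probes. Each time had 2 arrays with the dyes exchanged, so that replicate 1 carried the miR-210 cells in Cy3 and replicate 2 carried them in Cy5. The median spot signal of the miR-210 cells was 180.8 and 104.6 units on replicates 1 and 2 at 24 h, and 543.6 and 104.7 units at 48 h. The miR-67 cells gave 253.5 and 127.2 units at 24 h, and 869.5 and 132.1 units at 48 h. Between 59.6% and 93.2% of the spots stood well above background in a channel. The number of arrays limits the precision of every value. No probe carried the name of miR-210 or of its host transcript MIR210HG, so the level of the overexpressed microRNA was not analysed here. Ratios are given throughout as miR-210 cells over miR-67 cells.

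The main comparison asked which transcripts differed between the miR-210 and the miR-67 cells over both times. DIMT1, which encodes a methyltransferase of ribosomal RNA, was 1.87-fold lower in the miR-210 cells, a log2 ratio of −0.90 ± 0.06 (SE, n = 2 pair means), and lay between −0.95 and −0.81 on the 4 arrays. Among the other large falls were genes of secreted signalling proteins: BMPER, a regulator of bone morphogenetic proteins (−0.78 ± 0.07), IGFBP7 and IGFBP3, which bind insulin-like growth factors (−0.71 ± 0.06 and −0.62 ± 0.06), the cytokines IL11 (−0.71 ± 0.06) and IL15 (−0.64 ± 0.06), and the monocyte attractant CCL2 (−0.69 ± 0.06). VAMP7, a protein of vesicle fusion (−0.81 ± 0.06), FGFRL1, a receptor-like binder of fibroblast growth factors (−0.70 ± 0.07), ANXA3, an annexin (−0.66 ± 0.06), TUBA4A, an alpha-tubulin (−0.65 ± 0.06), and SLC16A3, the lactate exporter MCT4 (−0.64 ± 0.06), fell as well. ZSCAN18, a zinc finger gene, rose 1.84-fold (log2 0.88 ± 0.06), with a value of 0.57 when replicate 2 of 48 h was left out. COL21A1, a collagen (0.84 ± 0.06), SULF2, a sulfatase that edits heparan sulfate (0.77 ± 0.06), CPE, a carboxypeptidase of prohormone processing (0.76 ± 0.06), GRHL3, an epithelial transcription factor (0.71 ± 0.06), and PXDN, a peroxidase of basement membranes (0.70 ± 0.06), also rose. The remaining large rises were noncoding transcripts: SNORA12 (0.77 ± 0.07), MALAT1 (0.76 ± 0.10), RNU2-2 (0.71 ± 0.09), SCARNA13 (0.69 ± 0.07), SNORD116-19 (0.69 ± 0.07) and the pseudogene ANKRD20A8P (0.68 ± 0.06). Of these, RNU2-2 stood at 0.40 without replicate 2 of 24 h.

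limma called 3278 of 21155 genes at a Benjamini-Hochberg adjusted p under 0.05 over both times, 2155 higher and 1123 lower in the miR-210 cells. Higher genes made up 65.7% of the calls with loess normalization and 36.2% (924 of 2556) when each array was only centred on its median. The changes were small: the called genes had a median absolute log2 ratio of 0.24, with 38 genes at least 1.5-fold higher and 21 at least 1.5-fold lower. The sign was the same on all 4 arrays for 2499 of the called genes. This test used the spread between the pair means of 24 h and 48 h. With the spread between dye-swapped arrays in its place limma called 0 genes, with a smallest adjusted p of 0.0623 and 2724 genes at an unadjusted p under 0.05, and with Agilent's processed signals it called 0, with 5002 at an unadjusted p under 0.05. Leaving out replicate 1 or 2 of 24 h left 1409 and 258 calls, and leaving out replicate 1 or 2 of 48 h left 1903 and 387. The p-values and SE of the main test rest on the gap between the 2 pair means of a gene and on a spread shared by all genes (12.8 prior degrees of freedom). The gap between the arrays of a swap pair does not enter them. RPS20, at 0.26 ± 0.06, had ratios of −0.14 and 0.86 at 24 h and −0.22 and 0.54 at 48 h. The spread may be technical, since the labels do not say whether the arrays hold separate cultures, and the labels name 1 population of each kind.

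**Figure D1:**
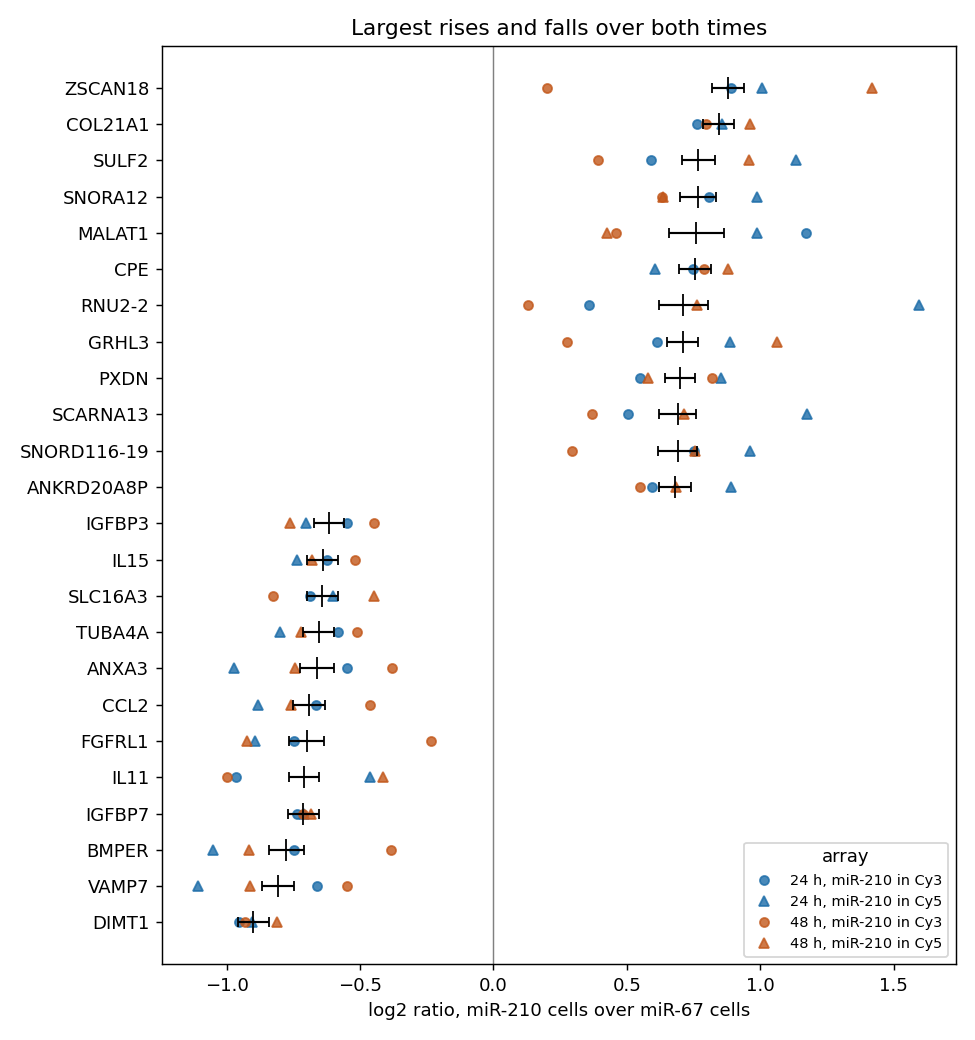
Log2 ratio of miR-210 over miR-67 cells (horizontal axis) for the 12 genes with the largest rises and the 12 with the largest falls over both times, with 1 point per array and the mean ± SE in black. Every point of a gene lies on the same side of 0, from DIMT1 at −0.90 to ZSCAN18 at 0.88.

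Transcripts described elsewhere as miR-210 targets were lower as a list, with a mean log2 ratio of −0.12 over the 42 measured members. Their median was −0.02, nearer to 0 than the mean. ISCU, a scaffold for iron-sulfur cluster assembly, fell 1.52-fold (−0.61 ± 0.06), and its 4 arrays lay between −0.64 and −0.56. NDUFA4, a subunit of cytochrome c oxidase (−0.56 ± 0.06), EHD2, a membrane-shaping ATPase (−0.56 ± 0.06), GPD1L, a relative of glycerol-3-phosphate dehydrogenase (−0.55 ± 0.07), and SDHD, a membrane anchor of succinate dehydrogenase (−0.46 ± 0.06), fell together with DIMT1 and FGFRL1. In all, 12 members fell and 2 rose, the kinase gene PIM1 (0.23 ± 0.06) and the corepressor gene SIN3A (0.19 ± 0.06), and the counts adjusted over the list alone were also 12 and 2. Both rises lost their calls when any 1 array was left out (0.13 to 0.25) and with median centring (0.15 and 0.11). The other 28 members did not pass. E2F3, a transcription factor of the cell cycle, fell by less (−0.24 ± 0.06) and missed the threshold when any 1 array was left out, with values from −0.30 to −0.18. The MYC antagonist MNT and the haem farnesyltransferase gene COX10 both stood at −0.03 (adjusted p of 0.740 and 0.789), but a second probe of MNT stood at 0.23. EFNA3 did not pass the signal filter. camera, a test of whether a list moved relative to the other genes, gave the list an adjusted p of 0.000516 with its preset correlation of 0.01. With a correlation estimated from the arrays the list was not called (adjusted p = 0.526 with an estimated correlation). The DIMT1 probe lies on chromosome 5 (61684548 to 61684607, hg19) and the ISCU probe on chromosome 12 (108963027 to 108963086, hg19).

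Few subunits of the respiratory chain passed the test. None of the 37 subunits of complex I passed the test, by either adjustment over all genes or adjusted over the list alone (0 each way), and the brightest, NDUFB2 and NDUFB9, stood at 0.08 and −0.02. Among 40 subunits of complexes II to V, 3 fell and 0 rose, also when adjusted over the list alone: NDUFA4, SDHD and the electron carrier CYCS (−0.35 ± 0.06), whose call was lost without replicate 2 of 24 h (−0.27) or of 48 h (−0.27). The 3 probes of CYCS ranged from −0.35 to −0.099, and the coordinates given for the one used lie on chromosome 2. The 3 probes of SDHD ranged from −0.48 to −0.43, and the coordinates given for the one used lie on chromosome 1. Neither list was called by camera (adjusted p of 0.593 and 0.514). For complexes II to V the median was 0.03, while the mean of −0.01 and the test pointed down. Of 27 genes of iron-sulfur assembly and iron handling, 3 rose and 3 fell (the same numbers adjusted over the list alone), with camera at an adjusted p of 0.483. FDXR, the reductase that feeds electrons to ferredoxin, rose (0.45 ± 0.06), and the mitochondrial iron importer SLC25A37 fell at its brightest probe (−0.39 ± 0.06), while its other probe stood at −0.032. ISCU fell as well.

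The list of glycolysis genes was lower by camera with the preset correlation. Of 21 genes of glycolysis and lactate export 4 fell and 0 rose (5 and 0 adjusted over the list alone): SLC16A3, the glucose transporter SLC2A1 (−0.46 ± 0.06), the lactate dehydrogenase gene LDHA (−0.28 ± 0.06) and the mutase gene PGAM1 (−0.20 ± 0.06). The list mean was −0.12, or −0.08 without replicate 2 of 48 h, and camera gave an adjusted p of 0.000516 (adjusted p = 0.526 with an estimated correlation). LDHA missed the threshold without replicate 1 of 24 h (−0.30), replicate 2 of 24 h (−0.26) or replicate 2 of 48 h (−0.20), and PGAM1 without the same arrays (−0.29, −0.12 and −0.13). Of 41 other genes that respond to hypoxia-inducible factor, 8 fell and 1 rose (10 and 4 adjusted over the list alone). PLOD2, a lysyl hydroxylase of collagen (−0.51 ± 0.06), and NDRG1, a stress-responsive gene (−0.45 ± 0.06), fell. CA9, the carbonic anhydrase often used as a marker of hypoxia, stood at −0.16 ± 0.06 (adjusted p of 0.0821), VEGFA at 0.09 ± 0.06 (0.326) and HIF1A at −0.10 ± 0.06 (0.245). camera did not call this list (adjusted p of 0.192), but did so without replicate 1 of 24 h (0.0451) or replicate 1 of 48 h (0.0428). Its median of 0.03 was above 0, while its mean of −0.03 and the test pointed down.

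The tricarboxylic acid cycle list was also lower by camera (mean −0.06, adjusted p of 0.0250; adjusted p = 0.640 with an estimated correlation), although only 2 of its 22 members fell, SDHD and the isocitrate dehydrogenase gene IDH3A (−0.21 ± 0.06), and 1 when adjusted over the list alone. Its camera call was lost without replicate 2 of 24 h (mean −0.048, adjusted p of 0.118) or of 48 h (mean −0.036, adjusted p of 0.138). IDH3A itself stood at 0.02 without replicate 2 of 24 h and −0.02 without replicate 2 of 48 h, where its dye effect is not cancelled. None of 20 fatty acid oxidation genes passed, nor when adjusted over the list alone (0), with a list mean of −0.0026 and a camera adjusted p of 0.538. Of 25 genes of cholesterol synthesis 3 rose and 1 fell (3 and 1 adjusted over the list alone), and camera gave an adjusted p of 0.593. The sterol carrier STARD4 rose (0.43 ± 0.06) and the synthase gene HMGCS1 fell (−0.31 ± 0.06), and both missed the threshold without replicate 2 of 24 h (0.36 and −0.24) or of 48 h (0.38 and −0.24).

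Genes that respond to p53 made up the only list that camera called higher with the preset correlation. Of 28 measured members 14 rose and 0 fell, or 17 and 0 adjusted over the list alone. GDF15, a stress-induced cytokine (0.67 ± 0.06), SPATA18, a gene of mitochondrial quality control (0.60 ± 0.06), BTG2, an antiproliferative gene (0.57 ± 0.06), and BBC3, which encodes the pro-apoptotic protein PUMA (0.57 ± 0.07), rose on all 4 arrays, with BTG2 at 0.38 without replicate 1 of 48 h. The cell cycle inhibitor CDKN1A, a classical p53 gene, rose by 0.19 ± 0.06 with an adjusted p of 0.0490. It lost the call when any 1 array was left out (0.09 to 0.29) and with median centring (0.13), and was picked after its value was seen. The list mean was 0.23, and camera gave an adjusted p of 3.04e-06 (adjusted p = 0.526 with an estimated correlation). Of 33 apoptosis regulators 7 rose and 0 fell (7 and 0 adjusted over the list alone), without a camera call (adjusted p of 0.514). They included BIK, a pro-apoptotic BCL2 relative (0.43 ± 0.06), and 3 genes that the p53 list also holds, BBC3, BAX and FAS. BAX (0.42 ± 0.09) rested largely on replicate 1 of 24 h (0.21 without it) and was not called without replicate 2 of 24 h (0.64) or of 48 h (0.36) either, and FAS (0.24 ± 0.06) lost its call when any 1 array was left out (0.19 to 0.29) and with median centring (0.16). For the repair of DNA double-strand breaks, 3 of 36 genes rose and 0 fell, BRCA2 (0.21 ± 0.06), BLM (0.19 ± 0.06) and XRCC2 (0.19 ± 0.06). Adjusted over the list alone 0 passed, leaving out any 1 array ended the 3 calls (values from 0.14 to 0.23), and camera gave an adjusted p of 0.942.

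Few proliferation genes passed the test. The list of G2/M and mitosis genes had a mean of −0.06 over 40 members, of which 1 fell and 0 rose (1 and 0 adjusted over the list alone). That gene was the spindle checkpoint gene MAD2L1 (−0.34 ± 0.06), which was not called without replicate 2 of 24 h (−0.20) or of 48 h (−0.12) and stood at −0.55 without replicate 1 of 48 h. camera gave this list an adjusted p of 0.00501 (adjusted p = 0.730 with an estimated correlation), and 0.287 and 0.311 without replicate 2 of 24 h and of 48 h, where the mean shrank to −0.018 and −0.0056. The G1/S and DNA replication list had a mean of −0.04 over 38 genes, with 2 lower and 0 higher by both adjustments, the second being adjusted over the list alone. These were E2F3 and the ribonucleotide reductase subunit RRM2 (−0.42 ± 0.06), a second probe of which stood at 0.04. The camera adjusted p of 0.0465 (adjusted p = 0.526 with an estimated correlation) passed by a narrow margin, and leaving out replicate 1 or 2 of 24 h, or replicate 1 or 2 of 48 h, gave 0.0781, 0.118, 0.141 and 0.103. Ribosome biogenesis genes that respond to MYC were lower (mean −0.08, 4 of 27 fell and 0 rose, 4 and 0 adjusted over the list alone), with camera at an adjusted p of 0.000516 (adjusted p = 0.526 with an estimated correlation). They included the assembly factor RRS1 (−0.31 ± 0.06), not called without replicate 2 of 24 h (−0.23) or of 48 h (−0.24), and LDHA, which the glycolysis list holds too. Cytosolic ribosomal proteins had a mean of 0.08, with 1 of 40 higher and 0 lower by both adjustments, again also adjusted over the list alone. That gene was RPS20 (0.26 ± 0.06), which stood at 0.01 without replicate 2 of 24 h and at 0.07 without replicate 2 of 48 h. camera did not call the list (adjusted p of 0.0999), but did so without replicate 1 of 24 h (mean 0.18, adjusted p of 5.67e-05) or of 48 h (mean 0.18, adjusted p of 7.12e-06).

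Several genes of inflammatory chemokines fell. Of 18 cytokines and other genes driven by NF-kB, 5 fell, 2 rose and 11 did not pass (6 fell and 2 rose adjusted over the list alone), with a list mean of −0.14. CCL2, CXCL5 (−0.58 ± 0.06) and CXCL1 (−0.48 ± 0.06), which attract monocytes and neutrophils, were lower on all 4 arrays, while TNFAIP3 (0.21 ± 0.06), an inhibitor of NF-kB, and SOD2 (0.19 ± 0.06), the mitochondrial superoxide dismutase, rose. Those 2 rises lost their calls when any 1 array was left out (0.12 to 0.25) and with the authors' table (0.18 and 0.20). With median centring SOD2 lost its call (0.11) and TNFAIP3 kept it (0.22). camera gave an adjusted p of 0.000516 (adjusted p = 0.526 with an estimated correlation). Of 26 interferon-stimulated genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a camera adjusted p of 0.760. The antiviral GTPase gene MX1 rose (0.32 ± 0.06) and the oligoadenylate synthetase gene OAS1 fell (−0.37 ± 0.07), and both missed the threshold without replicate 2 of 24 h (0.33 and −0.32) or of 48 h (0.29 and −0.25).

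None of the 3 lists of stress pathways was called by camera. Of 28 genes of the integrated stress response 7 rose and 8 fell (9 and 8 adjusted over the list alone). GDF15 rose, while the stress-induced chromatin regulator NUPR1 (−0.61 ± 0.06) and the cystine transporter SLC7A11 (−0.41 ± 0.06) fell. The transcription factor gene ATF3 rose at its brightest probe (0.39 ± 0.06), but its 4 probes ranged from −0.10 to 0.39. camera gave an adjusted p of 0.685, and its direction was down although the median and mean were both 0.01. Of 21 genes of the unfolded protein response 4 rose and 0 fell (4 and 0 adjusted over the list alone), with a camera adjusted p of 0.255. The endoplasmic reticulum chaperone gene CANX (0.39 ± 0.09) stood at 0.24 without replicate 2 of 24 h and at 0.41 without replicate 2 of 48 h, without a call in either case, and its other probe stood at −0.17. Of 26 genes that respond to NRF2, 4 rose and 2 fell (5 and 3 adjusted over the list alone), with a camera adjusted p of 0.514. The glutathione peroxidase gene GPX2 rose (0.49 ± 0.06), and SLC7A11 fell.

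Genes of the mesenchymal state and the matrix were mixed, with 4 of 28 higher and 9 lower (6 and 12 adjusted over the list alone) and a mean of −0.07. CCN1, a matrix protein induced by growth factors (−0.49 ± 0.06), and SNAI1, a repressor of E-cadherin (−0.46 ± 0.06), fell, while COL6A1, a collagen (0.43 ± 0.06), and ACTA2, a smooth muscle actin (0.40 ± 0.06), rose. SNAI1 was not called without replicate 2 of 48 h (−0.34), nor were COL6A1 and ACTA2 without replicate 2 of 24 h (0.35 and 0.37). camera gave an adjusted p of 0.00948 (adjusted p = 0.526 with an estimated correlation) and 0.0824 without replicate 2 of 48 h, where the mean was −0.043. Among 22 epithelial junction genes 3 rose and 3 fell (3 and 3 adjusted over the list alone), with the tight junction gene CLDN3 higher (0.45 ± 0.06) and its relative CLDN1 lower (−0.33 ± 0.06), the latter without a call when replicate 2 of 24 h (−0.22) or of 48 h (−0.30) was left out. camera gave an adjusted p of 0.538 and pointed down, while the median and mean were 0.01. None of 16 lung epithelial differentiation genes and none of 9 leukocyte markers passed, or passed when adjusted over the list alone (0 each). Their camera adjusted p was 0.593 in both cases, and the lung list had a median of 0.0034, while its mean of −0.0053 and the test pointed down. Of 4 fibroblast markers that could be measured COL1A1 fell (−0.30 ± 0.06), also adjusted over the list alone. It was not called without replicate 1 of 24 h (−0.13), replicate 2 of 24 h (−0.46) or replicate 1 of 48 h (−0.19). Of 4 endothelial markers, the secreted protein gene EGFL7 rose (0.23 ± 0.07) and the adhesion gene ESAM fell (−0.34 ± 0.06), also adjusted over the list alone. EGFL7 lost its call without any 1 array (0.08 to 0.38) and ESAM without replicate 2 of 24 h (−0.29) or of 48 h (−0.24). The fibroblast and endothelial lists had camera adjusted p-values of 0.192 and 0.514.

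**Figure D2:**
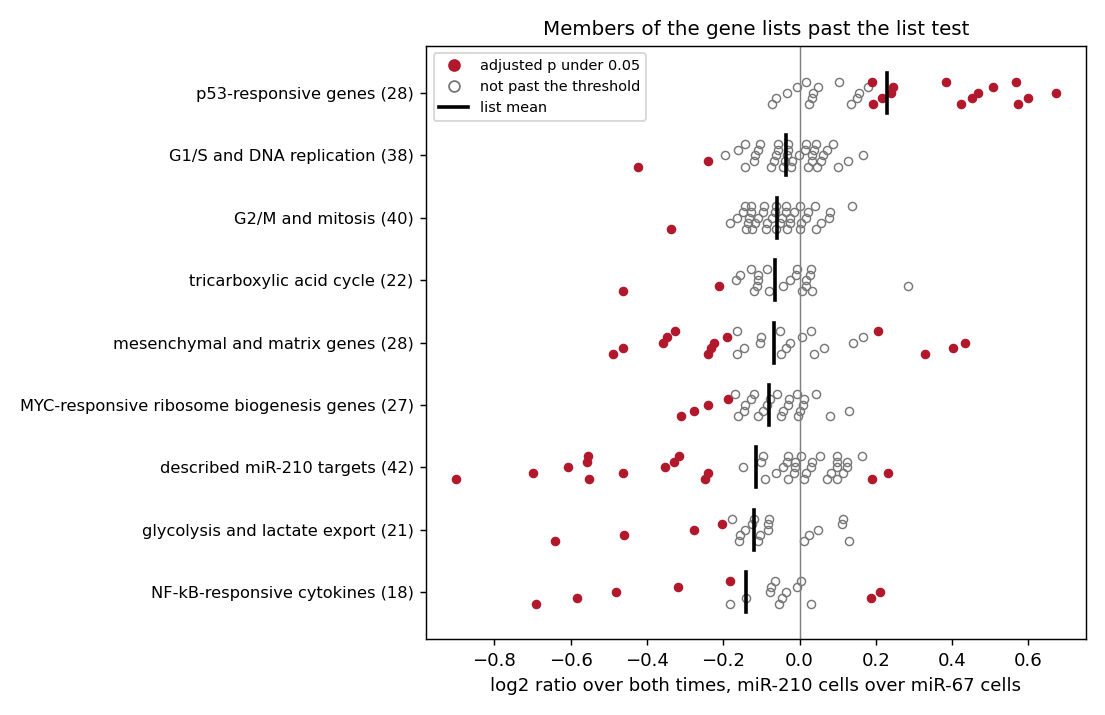
Log2 ratio over both times (horizontal axis) of each measured member of the 9 lists that camera called with a preset correlation, with the number of measured members in brackets. Filled points passed the limma test, open points did not, and bars mark list means, from −0.14 for the NF-kB-responsive cytokines to 0.23 for the p53-responsive genes.

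Probes for small nuclear and nucleolar RNAs gave higher signals in the miR-210 cells as a class, which was grouped after the values were seen. Whether these signals, and those of the other noncoding RNAs below, came from the mature RNAs was not tested. Of 52 measured, 27 rose and 1 fell, with a median log2 ratio of 0.21, and class medians of 0.17 and 0.42 on replicates 1 and 2 of 24 h and 0.046 and 0.20 on those of 48 h. On replicate 1 of 48 h the class stood hardly higher than all genes, whose median there was 0.041. The class median was above 0 under every scaling, from 0.19 to 0.31, but only 4 and 6 of these RNAs rose without replicate 2 of 24 h and of 48 h, and with Agilent's processed signals 0 did. Among single noncoding RNAs, picked after their values were seen, NEAT1, the scaffold of paraspeckles, rose over both times (0.49 ± 0.06). RMRP, the RNA of a mitochondrial and nucleolar endonuclease (0.56 ± 0.07), and RPPH1, the RNA of ribonuclease P (0.40 ± 0.06), rose too. RN7SK, a regulator of transcription elongation that already belongs to the 52 above, rose as well (0.52 ± 0.09). RN7SL1, the RNA of the signal recognition particle and the brightest of these (0.13 ± 0.06, adjusted p of 0.161), and the telomerase RNA TERC (0.17 ± 0.06, adjusted p of 0.0582) did not pass. Among ribosomal RNAs, RNA5-8SN5 (0.63 ± 0.10) and RNA28SN5 (0.35 ± 0.08) rose, whereas RNA18SN5 stood at −0.33 ± 0.15 (adjusted p of 0.153). RNA28SN5 rested on the arrays with miR-210 in Cy5 and stood at −0.07 without replicate 2 of 24 h and at −0.03 without replicate 2 of 48 h. RN7SK (0.19 and 0.22), RPPH1 (0.23 and 0.26), RMRP (0.33 and 0.44) and RNA5-8SN5 (0.24 and 0.47) likewise lost their calls without those arrays. Of 397 long noncoding RNA genes 60 rose and 14 fell, of 3731 lincRNA probes 357 and 117, and of 13467 protein-coding genes 1272 and 879, and these shares were not tested against each other.

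At 24 h alone, a fit with a dye effect for each probe placed MALAT1 at 1.08 ± 0.08, RNU2-2 at 0.98 ± 0.09, ZSCAN18 at 0.95 ± 0.11 and SNORA28 at 0.96 ± 0.08 on the log2 scale. RNU2-2 and SNORA28 rested largely on replicate 2, with ratios of 1.60 and 1.44 against 0.36 and 0.48 on replicate 1. DIMT1 stood at −0.93 ± 0.08, BMPER at −0.90 ± 0.08 and VAMP7 at −0.89 ± 0.08. APP, the gene of the amyloid precursor protein, had the lowest of these values at −1.26 ± 0.08, but the 2 probes of APP disagreed, standing at −0.57 and 0.40 over both times. These genes were named after their values were seen, because the test planned for 24 h, limma without a dye effect, called 0 of 21155 genes, with 1873 at an unadjusted p under 0.05. With the dye effect limma called 3313, 2022 higher and 1291 lower. The planned test called 37 and 3 genes without replicates 1 and 2 of 24 h, and 305 when one of the arrays of 48 h was left out, whichever it was.

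At 48 h, the same fit with a dye effect placed COL21A1 at 0.88 ± 0.08 and CPE at 0.84 ± 0.08, and DIMT1 at −0.87 ± 0.08, VAMP7 at −0.73 ± 0.08 and IL11 at −0.71 ± 0.08. ARFGAP2, a regulator of vesicle coats, stood at 1.14 ± 0.18, WHAMM, a promoter of actin assembly, at 0.82 ± 0.13 and FRAS1, a basement membrane gene, at −0.72 ± 0.12. All 3 rested on replicate 2, where the ratios were 2.27, 1.51 and −1.20 against 0.0042, 0.12 and −0.24 on replicate 1. The 3 probes of WHAMM ranged from 0.037 to 0.48 over both times, and the one used was the highest. The coordinates given for it lie on chromosome 15 (23200254 to 23200313, hg19), and whether it reads WHAMM itself was not tested. These genes too were named after their values were seen. The planned limma test called 0 of 21155 genes at 48 h, with 972 at an unadjusted p under 0.05, and with the dye effect limma called 1263, 869 higher and 394 lower. When one of the arrays of 24 h was left out, whichever it was, the planned test called 3 genes, and without replicate 1 or 2 of 48 h it called 97 and 6. In the fit with a dye effect, 496 genes were higher and 289 lower at both times, and 4 were called in opposite directions. Both calls of a gene share 1 estimate of its spread, so these numbers do not measure how alike the times were.

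The pair means of 24 h and 48 h had a correlation of 0.649 over 21155 genes, which are not independent replicates, and 71.4% of the genes had the same sign at both. Single arrays of the 2 times correlated at 0.635 and 0.688 in the same dye orientation, but at 0.0725 and −0.066 in opposite orientations. The likeness of the pair means thus came mainly from arrays of the same orientation, and 0.649 does not by itself measure a shared effect of miR-210. MALAT1 was higher by 1.08 at 24 h and 0.44 at 48 h, a difference of −0.64 ± 0.11 (adjusted p of 0.00994 in the fit with a dye effect). RNA18SN5 went from −0.86 to 0.19, a difference of 1.05 ± 0.11 (adjusted p of 2.29e-05), and HMOX1, the haem oxygenase gene, from 0.58 to −0.07, a difference of −0.65 ± 0.11 (adjusted p of 0.0129). These were chosen after their values were seen. The planned limma test of 48 h minus 24 h called 0 genes, with 101 at an unadjusted p under 0.05, and with the dye effect limma called 44, of which 23 were higher and 21 lower at 48 h. Leaving out replicate 1 or 2 of 24 h gave 0 and 2 calls in the planned test, and leaving out replicate 1 or 2 of 48 h gave 44 and 1. camera called no list in this difference, with a smallest adjusted p of 0.194.

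**Figure D3:**
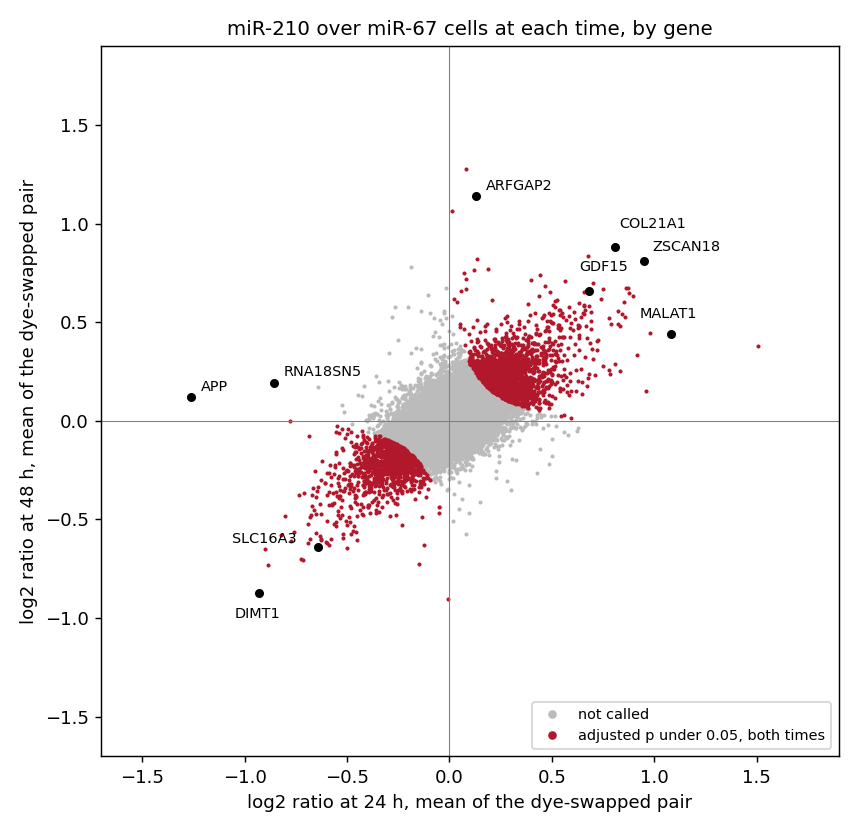
Log2 ratio of miR-210 over miR-67 cells at 48 h (vertical axis) against 24 h (horizontal axis) for each of 21155 genes, each value being the mean of a dye-swapped pair. Red points passed the limma test over both times, and APP and RNA18SN5 lie at −1.26 and −0.86 at 24 h but at 0.12 and 0.19 at 48 h.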

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

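The grouping of the small nuclear and nucleolar RNAs and with it all tests of that class (that of dye bias in pair means replaced tests on single arrays), the joint reading of the 2 tests of dye bias and the choice of the single genes named for their difference between times were made only after the results were seen. The effect of miR-210 differed between 24 h and 48 h for 44 genes in the limma fit with a dye effect, while the test without it called 0, with 101 genes at an unadjusted p under 0.05. These 44 were singled out because a test of the difference itself passed. In simulated data that fit made 128 calls, of which 31 (24.2%) were unchanged genes. That share depends on how many genes were changed in the simulation. With only 44 calls in the data, the share of unchanged genes among them may be larger.

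SNORA28, a nucleolar RNA, stood at 0.96 at 24 h and 0.15 at 48 h, a difference of −0.81 ± 0.12 (SE; limma adjusted p of 0.00177), and its arrays at 24 h were 0.48 and 1.44. DLST, a subunit of the oxoglutarate dehydrogenase complex, differed by −0.68 ± 0.11 (adjusted p of 0.00655). ANP32D, a relative of an acidic nuclear phosphoprotein, differed by −0.68 ± 0.12 (adjusted p of 0.00994). TAF5L, of a histone acetyltransferase complex, differed by −0.69 ± 0.13 (adjusted p of 0.0282), with arrays at 24 h of 0.78 and 0.08, and its other probe had the opposite sign over both times. ACTL8, an actin-like gene, differed by 0.85 ± 0.11 (adjusted p of 0.000637), with arrays at 48 h of −0.07 and 1.22. TAF15, an RNA-binding protein gene, differed by 0.82 ± 0.15 (adjusted p of 0.0224), with arrays at 48 h of −0.29 and 0.64. The coordinates given for its probe lie on chromosome 14. RNA18SN5, the RNA of the small ribosomal subunit, differed by 1.05 ± 0.11 (adjusted p of 2.29e-05). APP differed by 1.38 ± 0.11 (adjusted p of 1.45e-07), with arrays of −1.44 and −1.09 at 24 h and −0.06 and 0.30 at 48 h.

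The first pattern weighed was the set of 3278 genes called over both times. The ratio and the dye effect of the called genes had a squared correlation of 0.0223, within the bound set in advance against leftover dye bias. This value is near 0 whenever the ratios of the dye orientations spread alike across genes, with or without a shared effect. It therefore cannot decide whether dye bias was left over in the pair means. Turning the sign of the 48 h pair means left 0 calls, within the bound set in advance against a chance likeness of the times. This largely restates the correlation of 0.649 between the pair means, over genes that are not independent, so it cannot decide that question. The share of called genes with the same sign on all 4 arrays, 76.2%, lay between the bounds set in advance. It does not settle the question of dye bias, alone or read with the squared correlation. A dye effect can turn the sign of an array without moving a pair mean. Differences between the 2 transduced populations other than miR-210 may add to the set, and the design gives no further population to test this.

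The next pattern was the higher signal of probes for 52 small nuclear and nucleolar RNAs, with a median log2 ratio of 0.21. Of 10000 random sets matched on intensity 0% had a median as high, the central 95% lying between −0.02 and 0.06, so genes of like intensity did not share the shift. The class was grouped after its values were seen, so this share and those below are no independent support for a rise. The same share was 0% for the pair mean of 24 h and 0% for that of 48 h, in which a dye effect of equal size on both arrays cancels. A dye effect that differs between the arrays of a pair does not cancel, so dye bias stays open. The class median was higher with miR-210 in Cy5 than in Cy3 at 24 h (0.42 against 0.17) and at 48 h (0.20 against 0.046). On replicate 1 of 48 h alone 32.5% of the sets were as high, so the shift at 48 h rests on replicate 2. A different yield of such RNAs in the extracts of 1 time may account for part of the shift and cannot be told apart from an effect of miR-210, since the median at 48 h was 0.14, above 0 but below the 0.27 of 24 h.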

How the results depend on the processing

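The list tests with a dye effect and the sites in probe sequences were chosen after the data were seen; all other alternatives were planned. Over both times the 3278 calls became 0 with Agilent's processed signals (smallest adjusted p of 0.0846, 5002 genes at an unadjusted p under 0.05 in limma) and 0 with all 4 arrays in one fit, where the spread between dye-swapped arrays replaced that between times. The count was 4993 with a dye effect, including all 3278. It was 2556 with median centring (1848 shared), 3767 without background correction, 2792 with the authors' table (2417 shared), 4288 with no filter on dim probes (55.5% higher, over 34465 genes), 3371 with the stricter filter and 2724 with probes averaged. Leaving out 1 array gave 258 to 1903 calls, fewer without replicate 2 of either time; the cause was not tested. The median ratio of all genes lay between −0.02 and 0.04 in these settings.

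For 24 h the 0 calls became 3313 with a dye effect and 3 to 305 when 1 array was left out. For 48 h they became 1263 and 3 to 97, and for 48 h minus 24 h they became 44 and 0 to 44. All scalings and filters without a dye effect kept 0. In these tests the dye effect enters the spread unless it is fitted, and leaving out an array removes one orientation.

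Of the 27 lists, 9 were called with the preset correlation, 7 to 9 in the other scalings and filters and with averaged probes, and 10 with pair means. With an estimated correlation 0 were called. With a dye effect the counts were 10 with the preset and 0 with the estimated correlation. Leaving out 1 array gave 5 to 10. The described targets, glycolysis, p53, NF-kB and MYC lists kept their calls and directions in every setting with the preset correlation. G1/S lost its call with Agilent's signals (0.0894), no background correction (0.0506), the authors' table (0.0633), no filter (0.205) and averaged probes (0.0774), the tricarboxylic acid cycle with Agilent's signals (0.0527) and no filter (0.103), and the matrix list with no filter (0.103). G1/S lost it without any 1 array (0.0781 to 0.141), and G2/M (0.287 and 0.311) and the tricarboxylic acid cycle (0.118 and 0.138) without replicate 2 of 24 h or of 48 h. Ribosomal proteins gained one with no filter (0.00456), pair means (0.0140) and the dye effect (0.0172), and the unfolded protein response with no filter (0.0475).

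Of 94 called genes named by the rule, all kept their sign except IDH3A. It stood at −0.21, ranged from −0.44 to 0.0164 when 1 array was left out, and changed sign without replicate 2 of 24 h. Its ratios at 24 h and 48 h were 0.13 and 0.28 with miR-210 in Cy3, and −0.78 and −0.48 with miR-210 in Cy5. The sign of IDH3A thus followed the dye orientation. All 94 lost their calls with Agilent's signals and with 4 arrays in one fit. Median centring kept 82, averaged probes 88 and the table of the authors kept 85, and the other scalings, filters and the dye effect kept 94. Leaving out replicates 1 and 2 of 24 h kept 73 and 51, and those of 48 h kept 78 and 54. The planned search for sites in 3' UTRs, with its alternatives for longer and shorter sites, was not run. Signal over background limited replicates 2, where 59.6% to 62.9% of spots stood well above it.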

Other observations

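The site tests below, the check without DIMT1 and the tests in probe sequences in place of 3' UTRs were chosen after the data were seen. Some genes outside the lists carry a site for miR-210-3p in a 60-base probe, the complement of the seed with 1 further base (ACGCACA), and fell in the miR-210 cells. INF2, which promotes actin filament assembly, stood at −0.61 ± 0.06 (SE, n = 2 pair means; limma adjusted p of 3.28e-05) and kept its call when any 1 array was left out, with values from −0.70 to −0.52, but the average of its probes was −0.29. CSNK1E, a kinase of the circadian clock, stood at −0.34 ± 0.06 (adjusted p of 0.00221), PXDC1 at −0.29 ± 0.06 (0.0082) and CDR2L at −0.24 ± 0.06 (0.0142). CSNK1E was not called without replicate 2 of 24 h (−0.30) or of 48 h (−0.32), CDR2L was called only without replicate 1 of 48 h (−0.31), and PXDC1 was not called when any 1 array was left out (−0.31 to −0.27). With DIMT1, 5 of the 25 genes with such a site fell, and 1, the transcription factor gene SP9, rose (0.19 ± 0.06). The other 19 did not pass.

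The pattern tested was the lower level of these 25 genes against the other protein-coding genes with probes named through RefSeq accessions (13221 in all). All such probes of a gene were searched, so a site may lie in a probe other than the one that gave the ratio. The hypothesis was direct repression by miR-210-3p. The mean shift was −0.0800 on the log2 scale (two-sided permutation p of 0.00560 from 100000 permutations, adjusted p of 0.0257 over 5 site sets), with −0.12 for 10 genes with the longer site (ACGCACAA) and −0.04 for 65 genes with the shorter one. The tables argue against base composition, since 1.44% of 139 other heptamers of the same composition gave a shift as low. The criterion for direct repression written beforehand, a p under 0.05 and a longer site shifted at least as far, was met. It was set aside after the result was seen, because without DIMT1, the 1 described target among them, the shift was −0.05 (permutation p of 0.112), although 3.60% of the other heptamers were then as low, so direct repression may account for the shift but stays open. Repression by the control miR-67 needed a shift above 0. The 64 genes with its site shifted by −0.0102 (permutation p of 0.562), so no such shift was seen, but a small one stays open. The 49 genes with a site for miR-210-5p shifted by 0.01 (permutation p of 0.582).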
